A study of Mus musculus with 18 samples.

How the data were processed

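The submitters' processing notes name BWA 0.7.12-r1039, STAR 2.5.3a and RSEM (no version given) and the builds mm9 and mm10, without saying which tool ran on which build. Per the series description each library was sequenced 3 times, the first run was provided as alignments to mm9, and the analysis was done against mm10. It is not stated whether the runs were merged. The deposited table has 1 column of counts per Ensembl gene for each of the 18 libraries. The values as deposited were read here as RSEM expected counts, since RSEM is named and 22.96% of the values are not whole numbers. They were rounded for the count models. Gene symbols came from an annotation of build mm9 rather than mm10, so no coordinates are given. A symbol was found for 32722 of 50686 gene identifiers, 2655 of them share a symbol with another, and identifiers without one hold 6.59% of the counts. The labels do not state a stranded library kit, so overlapping antisense genes stay uncertain.

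Groups were read from the source names, and for the 3 doubtful libraries from the titles. Chosen before the data were examined were the groups, the check of the sort with 8 Paneth transcripts, the comparisons, 37 gene lists for cell types, metabolism, stress, cell cycle and immunity, the tests and most alternative settings. The library labelled young fasted stem 2 failed that check and was left out, which leaves 17 libraries for the comparisons within a population. The comparisons between populations used the 15 libraries of undisputed label.

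Differential expression was tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with robust dispersions, TMM factors, the default expression filter by population (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment over all genes of a comparison, called at an adjusted p under 0.05. Age and diet entered as added terms within each population. The fit of 17 libraries has 15386 genes, 12 coefficients, 5 residual degrees of freedom and a biological coefficient of variation of 0.125. The fit between populations has 15239 genes, 8 coefficients, 7 residual degrees of freedom and a coefficient of 0.131. Groups with 1 library are assumed to vary like the others. Log2 differences of tested comparisons are edgeR's, those without a test are of log2 CPM with a prior count of 2, and CPM of named genes are TMM-normalised, except in the check of the sort. DESeq2 1.42.0 was the alternative tool.

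Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison with at least 5 measured members. Differences without a test were ranked against 10000 random lists drawn within 20 bins of expression. The rule for named genes takes those past the adjusted p of 0.05 with a mean log2 CPM of at least 3 and the same sign in every matched pair, namely the 10 largest in each direction, up to 4 members of each list that passed or held at least 3 called members, and a fixed set that includes Lgr5, Olfm4, Lyz1, Mmp7, Cpt1a, Pdk4, Odc1 and Mki67. Of those, the text names a part.

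A simulation changed 200 genes for fasting in stem cells. EdgeR recovered 26.9%, 58.2% and 89.4% at folds of 1.5, 2 and 4 (3.88% false calls), DESeq2 23.9%, 55.2% and 87.9% (6.40%). For fasting in Paneth cells edgeR recovered 5.97%, 35.8% and 81.8%, and for the fasting response of progenitors against stem cells 14.9%, 50.7% and 77.3% at 8.41% false calls. Of 20 unchanged lists camera called 0, which does not cover correlated lists.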

Results

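Messenger RNA was measured in 18 libraries of epithelial cells sorted from crypts of the small intestine of C57BL/6 mice. The crypts are the pockets in which the epithelium renews itself, and 3 populations were sorted from them. Stem cells were sorted for high and progenitors for low fluorescence of a GFP reporter of Lgr5, the receptor that marks stem cells at the crypt base. Paneth cells, the granular cells that release antimicrobial peptides beside the stem cells, were sorted as positive for CD24 and c-Kit. The mice were young or old, and they were fed ad libitum, fasted for 24 h or refed after a fast. The series asks how age and diet act on these populations. Each combination of age, diet and population has 1 library. Exceptions are young fasted stem, with 2 by its labels, and young fed Paneth, named only in 1 source field. The libraries hold 10631300 (old fasted Paneth) to 16252700 (young fed stem) expected counts.

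The labels contradict each other for 3 libraries. Young fasted stem 1 and 2 carry the same title text and index, and the library described as a young fasted progenitor has a source field that reads young, fed and Paneth. A check set before the data were examined therefore compared 8 abundant Paneth transcripts, among them lysozyme and defensins, across libraries. Their mean log2(CPM + 1) was 5.89 over the stem, 7.74 over the progenitor and 13.39 over the Paneth libraries with undisputed labels. Young fasted stem 1 was at 5.87. The library labelled young fasted stem 2 was at 13.40 and was left out of every comparison. With it kept, the genes called for fasting in stem cells went from 163 to 1 and for refeeding from 1946 to 48. Young fasted progenitor was at 10.28, which is 2.54 from the progenitor and 3.10 from the Paneth mean, and it stayed in. These 8 transcripts took 22.1% of the counts of young fasted stem 2, 2.70% of young fasted progenitor, 0.217% to 0.983% of the other progenitor libraries, 0.0969% to 0.137% of the other stem libraries and 24.3% to 29.2% of the Paneth libraries. Before TMM scaling, the library labelled young fasted stem 2 had 28.6 CPM of Lgr5, against 244 in young fasted stem 1 and 35.6 in young fasted Paneth.

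**Figure D1:**
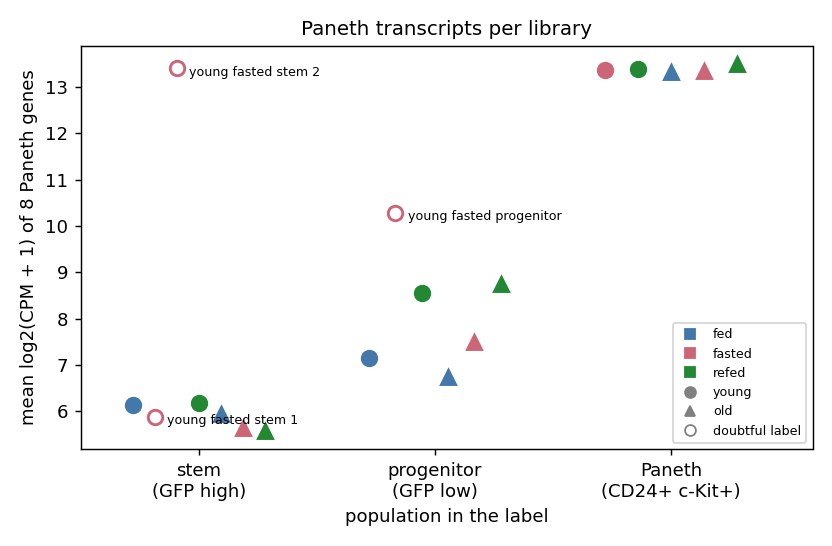
Mean log2(CPM + 1) of 8 Paneth cell transcripts (y axis) in each of the 18 libraries, by the population in the label (x axis), with circles for young and triangles for old mice, blue for fed, red for fasted and green for refed, and open symbols for the 3 doubtful labels. The upper open stem symbol, at 13.40, sits at the height of the Paneth libraries, and the open progenitor symbol, at 10.28, between them and the other progenitors.

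Nothing in the labels says whether libraries come from separate animals, so the p-values measure only the spread between these libraries. Before TMM scaling each had Xist (328 to 2418 CPM) and Y-linked Ddx3y (7.41 to 35.9), so RNA of both sexes, an unmodelled mix. With 1 library per group, the other age serves as replicate of a diet and the other diets of an age. The title numbers form 2 unbroken runs. The first holds all young stem and progenitor libraries and young fasted Paneth, the other young refed Paneth and all old libraries. Diets in stem cells and progenitors were thus compared within each run, but run and age cannot be told apart there.

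In the 15 undisputed libraries Paneth and stem cells differed in genes of secretion and proliferation. Lysozyme (Lyz1, ENSMUSG00000069515), the main antibacterial enzyme of the crypt, was at 278 ± 30.5 CPM in stem and 152965 ± 37771 CPM in Paneth libraries (mean ± SD, n = 5 each), a log2 difference of 9.02 (SE 0.52). Mmp7 differed by 6.93, Ang4 by 9.20 and Wnt3 by 5.83. Stem cells held more of Lgr5 (-1.72), Olfm4 (-2.71) and Fstl1 (-3.10). Before TMM scaling Lgr5 was 26.1 to 35.9 CPM in Paneth, 230 to 349 in stem and 17.5 to 64.5 in progenitor libraries. Such differences depend on scaling. Adjusted p for these 7 genes was 1.42e-10 to 1.37e-05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment), and all had the same sign in 4 of 4 matched pairs.

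List members not counted as higher or lower did not pass the test. By gene group, on the Paneth list 22 of 22 were higher (22 higher adjusted over the list alone, median 8.80, camera adjusted p = 8.61e-30, or 0.149 with an estimated correlation), with the surface marker Cd24a of the sort at 3.21. On the stem list 2 of 25 were higher and 22 lower (2 higher and 22 lower adjusted over the list alone, median -1.72, camera adjusted p = 1.34e-07, or 0.429 with an estimated correlation). Markers of other secretory cells were also higher in the Paneth gate, as was immune Ptprc. It was at 1.95 to 37.8 CPM before scaling (stem 0 to 0.77), so the gate may be mixed. On the goblet list 14 of 15 were higher and 1 lower, also adjusted over the list alone (median 3.19), with Atoh1 (3.86) and Spdef (4.10). Camera adjusted p was 1e-15, or 0.149 with an estimated correlation. On the enteroendocrine list 24 of 25 were higher and 1 lower, also adjusted over the list alone (median 3.50), with Reg4 at 7.72. Camera adjusted p was 1.56e-06, or 0.429 with an estimated correlation. On the tuft list 14 of 14 were higher, also adjusted over the list alone (median 5.57), with Avil at 5.34. Camera adjusted p was 1.42e-18, or 0.147 with an estimated correlation. Genes of endoplasmic reticulum quality control were higher too: on the unfolded protein response list 18 of 19 were higher (18 higher adjusted over the list alone, median 1.21, camera adjusted p = 4.84e-10, or 0.386 with an estimated correlation), with Edem1 (2.70), Herpud1 (2.43) and Sel1l (2.11). Genes of dividing cells were lower: on the mitosis list 1 of 25 was higher and 24 lower (1 higher and 24 lower adjusted over the list alone, median -1.82, camera adjusted p = 1.22e-08), with the proliferation antigen Mki67 at -1.94, and on the DNA replication list 1 of 30 was higher and 29 lower (1 higher and 29 lower adjusted over the list alone, median -1.76, camera adjusted p = 1.45e-11). With an estimated correlation, adjusted p = 0.429. On the ribosomal protein list 1 of 79 was higher and 76 lower (1 higher and 76 lower adjusted over the list alone, median -1.07, camera adjusted p = 9.27e-22, or 0.429 with an estimated correlation). In all, 5205 genes were higher and 5161 lower of 15239 tested. All 16 named genes passed without any 1 library.

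Progenitors held less of stem genes and more of secretory genes than stem cells. Lgr5 (ENSMUSG00000020140) was at 24.3 ± 13.9 CPM in progenitors and 205 ± 35.7 CPM in stem cells (mean ± SD, n = 5 each, log2 difference -3.19, SE 0.16), Olfm4 differed by -2.003, the stem receptor Tnfrsf19 by -2.78 and Fstl1 by -2.61. Goblet genes were higher, among them the lectin Zg16 (4.11), the mucus protein Fcgbp (3.65) and Atoh1 (2.52). Hormone cell genes were higher as well, with cholecystokinin (Cck) at 4.19, Tph1, the serotonin-synthesis enzyme, at 3.82 and Reg4 at 2.60. Adjusted p for these 10 genes was 3.72e-07 to 0.000403 (edgeR), with the same sign in 5 of 5 matched pairs. Mki67 was not separated from 0 (-0.23, edgeR adjusted p = 0.377).

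By gene group, on the stem list 25 of 25 were lower (25 lower adjusted over the list alone, median -1.51, camera adjusted p = 6.64e-35), and on the Wnt pathway list 3 of 22 were higher and 16 lower (3 higher and 17 lower adjusted over the list alone, median -1.21, camera adjusted p = 1.02e-14). These had adjusted p = 0.0975 and 0.0403 with an estimated correlation. On the goblet list 14 of 15 were higher and 1 lower (14 higher and 1 lower adjusted over the list alone, median 3.07, camera adjusted p = 1.38e-40), on the enteroendocrine list 25 of 25 were higher (25 higher adjusted over the list alone, median 3.58, camera adjusted p = 5.8e-16), and on the enterocyte list 21 of 24 were higher (21 higher adjusted over the list alone, median 1.87, camera adjusted p = 4.25e-08), with the brush border phosphatase Alpi at 3.20. They had adjusted p = 0.0403, 0.366 and 0.484 with an estimated correlation. Paneth and tuft markers were higher too. On the Paneth list 20 of 22 were higher (20 higher adjusted over the list alone, median 1.87, camera adjusted p = 2.1e-09), with Lyz1 at 1.99, and on the tuft list 12 of 14 were higher (12 higher adjusted over the list alone, median 1.64, camera adjusted p = 5.13e-05), with the kinase Dclk1 at 2.17. Camera gave adjusted p = 0.484 with an estimated correlation. On the DNA replication list 13 of 30 were lower (13 lower adjusted over the list alone, median -0.39, camera adjusted p = 0.00252, or 0.779 with an estimated correlation), and on the mitosis list 3 of 25 were lower (0 adjusted over the list alone, median -0.30, camera adjusted p = 0.0686). That last list passed camera without young refed or old refed progenitor, old fed or old fasted stem (adjusted p = 0.0329, 0.042, 0.0165 and 0.0129) or with no expression filter (0.0114). In all, 3640 genes were higher and 2981 lower of 15239, a split that upper-quartile factors turned to 3053 and 3935. All 13 named genes passed without any 1 library. Of the calls that camera made over all comparisons at its preset correlation of 0.01, those on the goblet and Wnt lists here and on the PPAR target list in fasted stem cells held with an estimated correlation.

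Fasting for 24 h was compared with ad libitum feeding within each population, with age as a term. In stem cells the genes that rose included genes of fatty acid use. Pdk4 (ENSMUSG00000019577), the kinase that keeps pyruvate out of the citrate cycle, was at 2.67 ± 0.204 CPM in fed and 72.5 ± 26.8 CPM in fasted libraries (mean ± SD, n = 2 each), a log2 rise of 4.75 (SE 0.17). Angptl4, an inhibitor of lipoprotein lipase, rose by 4.14, the acyl-CoA thioesterases Acot1 and Acot2 by 2.99 and 2.68, malic enzyme Me1 by 2.61 and Acacb, an acetyl-CoA carboxylase, by 3.04. Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 1.35, and the oxidation enzymes Acadl, Hadhb, Acadvl and Hadha rose by 2.42, 1.83, 1.72 and 1.59. Scd2, a fatty acid desaturase, fell by 3.69. The oxidase Nox1 was at -1.64, nitric oxide synthase Nos2 at -1.23 and the surface protein Cd177 at -1.56. All 15 genes passed with the same sign at both ages, at adjusted p of 3.85e-08 to 0.048 (edgeR).

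On the PPAR target list, genes under the fatty acid receptors, 12 of 22 rose (19 up adjusted over the list alone, median 1.70, camera adjusted p = 2.12e-108) in fasted stem cells, and on the fatty acid oxidation list 15 of 25 rose (23 up adjusted over the list alone, median 0.83, camera adjusted p = 1.4e-80). With an estimated correlation, adjusted p = 0.0364 and 0.054. On the mitosis list 12 of 25 fell (24 down adjusted over the list alone, median -0.63, camera adjusted p = 9.51e-38, or 0.109 with an estimated correlation), with Mki67 at -0.68. Oxct1, the enzyme that consumes ketone bodies, fell by 0.87, and Fbp1, of gluconeogenesis, rose by 0.95. On the fatty acid synthesis list 2 of 14 rose and 2 fell (2 up and 6 down adjusted over the list alone, median -0.09, mean 0.03, camera's direction down, camera adjusted p = 0.478), with the lipid regulator Srebf1 at -0.48, and that list passed camera with no age term (adjusted p = 0.00592). Stem genes did not pass: on the stem list 0 of 25 passed (0 adjusted over the list alone, median -0.04, camera adjusted p = 0.71), and Lgr5 and Olfm4 were at -0.04 and -0.47 (adjusted p = 0.987 and 0.612 by edgeR). The stem list passed camera without old fed stem (adjusted p = 0.0422). Without young fed stem or young fasted stem 1 its median (0.13 and 0.04) and Lgr5 (0.36 and 0.21) turned positive, as they did without the doubtful libraries (0.03 and 0.20). Adjusted p for Mki67, Oxct1, Fbp1 and Srebf1 was 0.000591 to 0.038 by edgeR. In all, 103 genes rose and 60 fell of 15386 tested. The count of 163 moved over 1.5 times without young fasted stem 1 (32), young fed (31), old fed (85) or old fasted stem (69). Of the 19 named calls, 13 held without any 1 library. Calls were lost without young fasted stem 1 (6, 0.388), young fed (6, 0.352), young refed (2, 0.0675), old fed (2, 0.225), old fasted (4, 0.231) and old refed stem (2, 0.0679), and with no expression filter (1, 0.0736), no age term (4, 0.756) and a separate fit per population (1, 0.138) (number lost, highest edgeR adjusted p). DESeq2 lost Srebf1 (adjusted p = 0.0884). Without the doubtful libraries 27 genes passed (25 shared), and 7 named calls were lost (edgeR adjusted p up to 0.526).

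In progenitors Pdk4 rose from 1.84 ± 0.00974 to 61.1 ± 14.3 CPM (mean ± SD, n = 2 each, log2 difference 5.04, SE 0.18). Cyp4a10, a fatty acid omega-hydroxylase, rose by 6.53, the fatty acid carrier Fabp1 by 4.48, Angptl4 by 3.99, Me1 by 3.59, Acot1 by 3.26, Acadl by 2.17 and Cpt1a by 1.13. Scd2 fell by 3.43, Nox1 and its activator Noxa1 by 2.19 and 1.26, Olfm4 by 1.35, Cd177 by 1.20 and Oxct1 by 0.87. Adjusted p was 8.9e-09 to 0.0465 for these 14 genes (edgeR). Signs were the same at both ages. Lgr5 was at -0.81 (adjusted p = 0.339 by edgeR), passed without old fed progenitor (-1.54, 0.00717) and turned positive without young fed progenitor (0.10, 0.917).

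On the PPAR target list 20 of 22 rose (22 up adjusted over the list alone, median 2.42, camera adjusted p = 1.85e-90), and on the fatty acid oxidation list 25 of 25 rose (25 up adjusted over the list alone, median 1.14, camera adjusted p = 3.01e-61). These had adjusted p = 0.0502 and 0.0921 with an estimated correlation. On the mitosis list 18 of 25 fell (25 down adjusted over the list alone, median -0.59, camera adjusted p = 7.2e-19), with Mki67 at -0.60, and on the DNA replication list 20 of 30 fell (26 down adjusted over the list alone, median -0.47, camera adjusted p = 3.72e-16), with Mcm5 at -0.72 and Rrm2 at -0.67. They had adjusted p = 0.203 and 0.221 with an estimated correlation. On the stem list 8 of 25 fell (15 down adjusted over the list alone, median -0.54, camera adjusted p = 3.4e-09, or 0.374 with an estimated correlation). Markers of other cells moved in the same libraries. On the enterocyte list 9 of 24 rose (15 up adjusted over the list alone, median 1.71, camera adjusted p = 7.51e-15, or 0.306 with an estimated correlation). The 8 Paneth transcripts took 2.70% of counts in young fasted, 0.269% in young fed, 0.368% in old fasted and 0.217% in old fed progenitor. On the tuft list 12 of 16 rose (13 up adjusted over the list alone, median 1.86, camera adjusted p = 1.98e-24), with Sh2d6 (2.97) and Avil (1.38), and on the Paneth list 5 of 22 rose (16 up adjusted over the list alone, median 2.54, camera adjusted p = 1.43e-09), with Ang4 at 2.33. Camera gave adjusted p = 0.105 and 0.34 with an estimated correlation. Lyz1 was at 2.54 (adjusted p = 0.0817 by edgeR) and passed without young refed (adjusted p = 0.0453), old fasted (1e-04) or old refed progenitor (0.0452) or with no age term (0.0374). Adjusted p of the other genes of these lists was 3.63e-05 to 0.0205 by edgeR. In all, 809 genes rose and 616 fell of 15386, a split of 743 and 285 by DESeq2. The count of 1425 moved over 1.5 times without young fed (187), young fasted (182) or old fasted progenitor (416). Of the 20 named calls, 16 held without any 1 library. Losses of calls came without young fed (4, 0.293), young fasted (4, 0.284), young refed (1, 0.0513), old fed (1, 0.0574), old fasted (3, 0.141) and old refed progenitor (1, 0.0513), and with no expression filter (3, 0.154), no age term (6, 0.472) and a separate fit per population (4, 0.262) (number lost, highest edgeR adjusted p). Leaving out the doubtful libraries, 105 genes passed (103 shared), and 5 named calls were lost (edgeR adjusted p up to 0.329).

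In Paneth libraries the fed state is held by 1 old library, so 1 matched pair gives a direction. Pdk4 rose from 4.39 CPM in old fed Paneth to 75.7 ± 26.6 CPM in the fasted libraries (mean ± SD, n = 2, log2 difference 3.70, SE 0.25). Acot1 rose by 2.83, Me1 by 1.81, Eci2, an isomerase of fatty acid oxidation, by 1.79, Acadl by 1.65 and Cpt1a by 1.40. Slc28a2, a nucleoside transporter, fell by 3.13, Scd2 by 2.24, Fkbp11, a prolyl isomerase of the secretory pathway, by 1.59 and Oxct1 by 1.09. The Paneth products Lyz1 and Mmp7 were at -0.18 and 0.26 (adjusted p = 0.957 and 0.939, Lyz1 at 0.14 without old fasted Paneth), against 6.71e-05 to 0.0424 for the 10 genes above (edgeR). On the PPAR target list 6 of 22 rose (13 up adjusted over the list alone, median 0.96, camera adjusted p = 6.93e-32), on the fatty acid oxidation list 7 of 25 rose (15 up adjusted over the list alone, median 0.53, camera adjusted p = 5.89e-21). With an estimated correlation, adjusted p = 0.159 and 0.264. On the Paneth list 0 of 22 passed (1 down adjusted over the list alone, median -0.08, mean -0.13, camera's direction up, camera adjusted p = 0.904). On the mitosis list 2 of 25 fell (15 down adjusted over the list alone, median -0.57, camera adjusted p = 1.32e-13, or 0.336 with an estimated correlation), with Birc5 at -1.05. On the tuft list 4 of 16 rose (11 up adjusted over the list alone, median 1.17, camera adjusted p = 4.62e-26, or 0.159 with an estimated correlation), with Sh2d6 at 1.45 (edgeR adjusted p of Birc5 and Sh2d6 0.00769 to 0.0424). In all, 50 genes rose and 48 fell. The count of 98 moved over 1.5 times without young fasted (29), young refed (36), old fasted (14) or old refed Paneth (33). Of the 12 named calls, 5 held without any 1 library but old fed Paneth. Genes failed without young fasted (3, 0.139), young refed (1, 0.136), old fasted (7, 0.203) and old refed Paneth (2, 0.137), and with a CPM filter (1, 0.0537), no age term (5, 0.812) and a separate fit per population (1, 0.0837) (number lost, highest edgeR adjusted p). On the undisputed libraries alone, 64 genes passed (57 shared), and 1 named call was lost (edgeR adjusted p up to 0.0593). With the run of title numbers as a term, an alternative chosen after seeing the data, 35 genes passed and 2 of the named calls were lost (adjusted p up to 0.142 by edgeR).

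**Figure D2:**
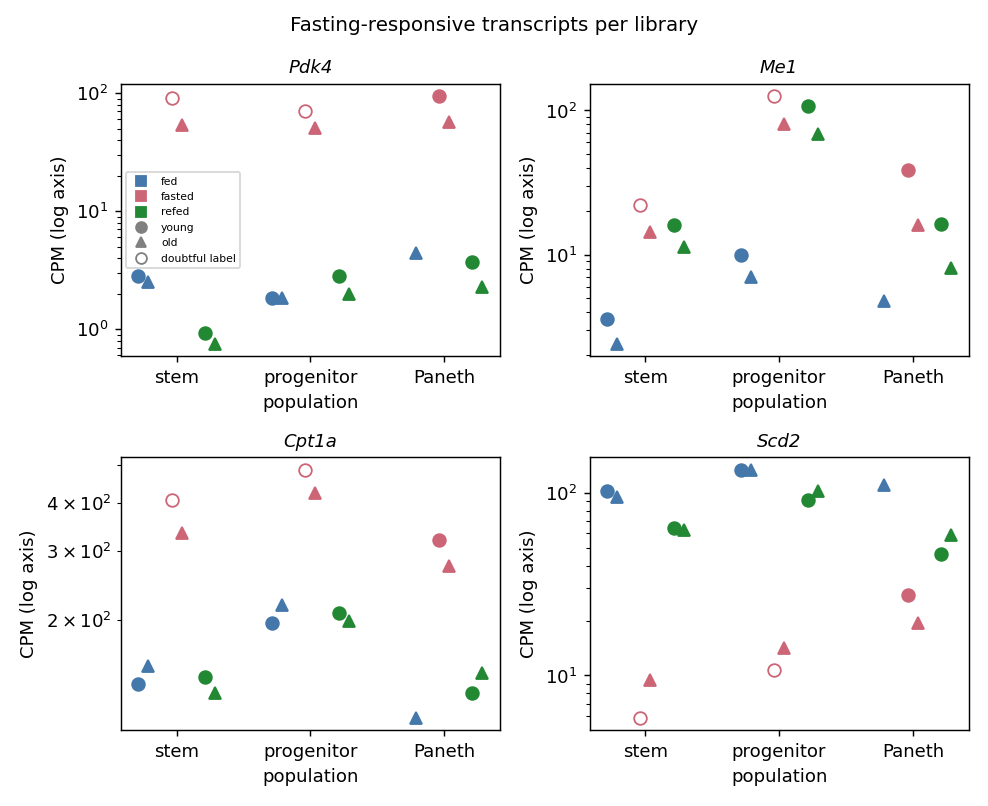
CPM (log axis, TMM-normalised) of Pdk4, Me1, Cpt1a and Scd2 in each of the 17 libraries compared, by population (x axis) and diet (blue fed, red fasted, green refed), with circles for young and triangles for old mice. Pdk4 in stem cells was at 2.67 ± 0.204 CPM fed, 72.5 ± 26.8 CPM fasted and 0.842 ± 0.132 CPM refed (mean ± SD, n = 2 each).

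Whether fasting acted differently between populations was tested directly. Between progenitors and stem cells 0 genes passed edgeR's quasi-likelihood test (1504 at an unadjusted p under 0.05, smallest adjusted p 0.0646), whereas DESeq2 called 34. Without 1 library the edgeR count was 1 (young fed stem), 15 (young refed), 178 (old fed), 49 (old fasted) or 8 (old refed progenitor). Between Paneth and stem cells 4 genes passed (1441 at an unadjusted p under 0.05, 16 by DESeq2, of which 6 were higher and 10 lower). The 4 fall outside the rule for named genes and were chosen after their values were seen. Fkbp11 responded by -2.49 (SE 0.29) in Paneth relative to stem cells, and 3 unnamed genes responded by 1.64 (ENSMUSG00000097142), 1.45 (ENSMUSG00000098557) and -2.63 (ENSMUSG00000100801), at adjusted p of 5.26e-05 to 0.0153 by edgeR. The count of 4 moved over 1.5 times without young fed stem (1), young fasted stem 1 (1), old fed stem (1), old fasted stem (1), old fasted Paneth (2) or old refed Paneth (1). Of the 4 named calls, 1 held without any 1 library but old fed Paneth. Calls were lost without young fed stem (3, 0.117), young fasted stem 1 (3, 0.124), young fasted Paneth (1, 0.0627), young refed stem (1, 0.0531), young refed Paneth (1, 0.0634), old fed stem (3, 0.0692), old fasted stem (3, 0.0863), old fasted Paneth (3, 0.132), old refed stem (1, 0.0544) and old refed Paneth (3, 0.065), and with no age term (4, 0.556) (number lost, highest edgeR adjusted p). Without the doubtful libraries 1 gene passed (1 shared), and 3 named calls were lost (edgeR adjusted p up to 0.196).

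Refeeding was compared with fasting in the same way. Mitochondrially encoded transcripts took, young then old, 6.76% and 5.72% of counts in fasted and 5.16% and 5.07% in refed stem cells, 6.28% and 6.56% against 4.84% and 4.86% in progenitors, and 3.14% and 2.88% against 2.27% and 1.93% in Paneth cells. In stem cells the genes that rose included cytosolic chaperones. The inducible chaperone gene Hspa1b was at 0.896 ± 0.0160 CPM in fasted and 204 ± 165 CPM in refed libraries (mean ± SD, n = 2 each, log2 difference 7.66, SE 1.30) and its near-identical copy Hspa1a at 6.73, so reads may be split between the pair. Hsph1 rose from 50.5 ± 4.94 to 579 ± 193 CPM (3.49) and Dnaja1 by 1.92. Scd2 rose by 3.05 and fatty acid synthase Fasn by 1.09. Pdk4 fell by 6.39, Angptl4 by 2.78, Acot2 by 2.09 and Cpt1a by 1.44. Adjusted p was 7.53e-09 to 0.0221 (edgeR). Signs were the same at both ages.

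On the unfolded protein response list 16 of 19 rose (17 up adjusted over the list alone, median 0.74, camera adjusted p = 4.45e-18, or 0.269 with an estimated correlation), with the chaperone Hspa5 at 1.55 and Creld2 at 1.77. Beside it, on the goblet list 1 of 15 rose and 1 fell (1 up and 1 down adjusted over the list alone, median 0.83, camera adjusted p = 0.105) and on the enteroendocrine list 0 of 25 passed (0 adjusted over the list alone, median 1.24, camera adjusted p = 0.0258, or 0.747 with an estimated correlation). The goblet list passed camera without young fasted stem 1 (adjusted p = 0.0215), young fed (0.000281), old fed (0.000279) or old refed stem (8.25e-05), without the doubtful libraries (median 1.35, adjusted p = 0.0276) or with no expression filter (0.0434), and the enteroendocrine list did not pass without young refed (median 0.14, adjusted p = 0.952) or old fasted stem (0.191). On the cholesterol synthesis list 12 of 23 rose and 1 fell (17 up and 1 down adjusted over the list alone, median 0.54, camera adjusted p = 1.07e-11, or 0.269 with an estimated correlation), with Sqle at 1.32 and Insig1 at 1.51. On the ribosome biogenesis list 15 of 25 rose (18 up and 1 down adjusted over the list alone, median 0.39, camera adjusted p = 1.41e-09, or 0.269 with an estimated correlation), with Rrp12 at 1.07. Of the polyamine enzymes, Srm was at 1.10 and the rate-limiting Odc1 at 0.40. On the FoxO target list, genes that insulin holds down, 9 of 19 fell (9 down adjusted over the list alone, median -0.46, camera adjusted p = 3.52e-12, or 0.116 with an estimated correlation), with the insulin receptor Insr at -0.79. Among PPAR targets, 11 of 22 fell (14 down adjusted over the list alone, median -0.87, camera adjusted p = 4.61e-22, or 0.269 with an estimated correlation). Mki67 rose by 0.45, while on the mitosis list 1 of 25 rose (1 up adjusted over the list alone, median 0.07, camera adjusted p = 0.577). That list passed camera without young refed stem (adjusted p = 0.000858) and turned negative without old fasted stem (median -0.07) or old refed stem (-0.12). Adjusted p of the genes named with these lists was 0.000169 to 0.0207 by edgeR. In all, 1205 genes rose and 741 fell, against 839 and 928 with upper-quartile factors and 874 in all by DESeq2. The count of 1946 moved over 1.5 times without young fasted stem 1 (150), young refed (112), old fasted (773) or old refed stem (769). Of the 19 named calls, 12 held without any 1 library. Losses of calls came without young fasted stem 1 (6, 0.207), young refed (6, 0.287), old fasted (3, 0.127) and old refed stem (1, 0.205), and with a separate fit per population (1, 0.0989) (number lost, highest edgeR adjusted p). Leaving out the doubtful libraries, 55 genes passed (54 shared), and 9 named calls were lost (edgeR adjusted p up to 0.256).

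In progenitors, refeeding against fasting raised Hspa1a (7.71, SE 0.61), Hspa1b (7.50), Hsph1 (3.90, from 36.4 ± 7.69 to 553 ± 178 CPM, mean ± SD, n = 2 each), Dnaja1 (1.92), Scd2 (2.97), Fasn (0.95) and the clock gene Per2 (1.91). Pdk4 fell by 4.65, Angptl4 by 2.97, Acot2 by 1.94, the gluconeogenic enzyme Pck1 by 1.78 and Cpt1a by 1.16. Odc1 did not pass (0.23, adjusted p = 0.14, against 6.23e-08 to 0.0302 for the 12 genes above, edgeR). The sign was the same at both ages. On the unfolded protein response list 15 of 19 rose (16 up adjusted over the list alone, median 0.74, camera adjusted p = 6.14e-19), with Creld2 at 1.67, and on the ribosome biogenesis list 12 of 25 rose (19 up and 1 down adjusted over the list alone, median 0.37, camera adjusted p = 1.83e-09), with Nolc1 at 0.71. These had adjusted p = 0.243 and 0.225 with an estimated correlation. On the PPAR target list 9 of 22 fell (17 down adjusted over the list alone, median -0.72, camera adjusted p = 1.36e-22) and on the FoxO target list 3 of 19 fell (1 up and 3 down adjusted over the list alone, median -0.30, camera adjusted p = 3.12e-06). They had adjusted p = 0.225 with an estimated correlation. Tuft markers fell with these: on the tuft list 5 of 16 fell (6 down adjusted over the list alone, median -0.74, camera adjusted p = 1.25e-06, or 0.304 with an estimated correlation) (edgeR adjusted p of Creld2 and Nolc1 0.000517 to 0.0016), and the 8 Paneth transcripts took 2.70% of the counts of young fasted, 0.757% of young refed, 0.368% of old fasted and 0.983% of old refed progenitor. In all, 898 genes rose and 547 fell, against 334 and 344 by DESeq2, 675 and 620 with RLE factors and 600 and 687 with upper-quartile factors. The count of 1445 moved over 1.5 times without young fasted (101), young refed (280), old fasted (536) or old refed progenitor (698). Of the 14 named calls, 9 held without any 1 library. Genes failed without young fasted (5, 0.237), young refed (4, 0.126), old fasted (3, 0.131) and old refed progenitor (1, 0.161), and with no expression filter (2, 0.0954), no age term (1, 0.0591) and a separate fit per population (1, 0.15) (number lost, highest edgeR adjusted p). On the undisputed libraries alone, 44 genes passed (40 shared), and 6 named calls were lost (edgeR adjusted p up to 0.28).

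In Paneth cells, refeeding against fasting raised the same chaperones, with Hspa1a at 7.44, Hspa1b at 6.66 and Hsph1 at 3.93 (from 21.98 ± 1.51 to 338 ± 68.9 CPM, mean ± SD, n = 2 each, SE 0.33). Chaperones of the endoplasmic reticulum rose too, Hspa5 by 1.87, Hyou1 by 1.87, Dnajb9 by 1.89 and Creld2 by 2.26. Pdk4 fell by 4.66, Acot1 by 2.44, Acot2 by 2.36 and Cpt1a by 1.11. Adjusted p was 1.56e-07 to 0.0193 (edgeR). Signs were the same at both ages. On the unfolded protein response list 16 of 19 rose (17 up adjusted over the list alone, median 0.998, camera adjusted p = 2.59e-34), and on the ribosome biogenesis list 14 of 25 rose and 1 fell (14 up and 2 down adjusted over the list alone, median 0.42, camera adjusted p = 3.74e-09). Camera gave adjusted p = 0.15 and 0.245 with an estimated correlation. On the mitosis list 24 of 25 fell (24 down adjusted over the list alone, median -1.14, camera adjusted p = 1.29e-32, or 0.15 with an estimated correlation), with Mki67 at -1.02 and Kif11 at -1.44. Beside it, on the stem list 1 of 25 rose and 4 fell (1 up and 5 down adjusted over the list alone, median -0.31, camera adjusted p = 0.0785), with Olfm4 at -0.96 (771 to 457 CPM in young and 791 to 352 in old mice). Olfm4 did not pass (edgeR adjusted p = 0.0558), but did with a CPM filter (0.0497), no age term (0.0323) or a separate fit per population (0.000575). That stem list passed camera without old fasted Paneth (adjusted p = 0.0484) or with a separate fit per population (0.0414). Among PPAR targets, 13 of 22 fell (13 down adjusted over the list alone, median -0.94, camera adjusted p = 8.49e-17) and on the FoxO target list 8 of 19 fell (10 down adjusted over the list alone, median -0.41, camera adjusted p = 1.45e-08), with Irs2 at -1.10. With an estimated correlation, adjusted p = 0.271 and 0.15. On the tuft list 16 of 16 fell (16 down adjusted over the list alone, median -1.38, camera adjusted p = 8.27e-25, or 0.15 with an estimated correlation). Fasn, Srm and Odc1 rose by 0.94, 1.43 and 0.56 (edgeR adjusted p of Mki67, Kif11, Irs2 and these 3 genes 6.5e-05 to 0.00301). In all, 1127 genes rose and 1413 fell, and DESeq2 called 1625. The count of 2540 moved over 1.5 times without young fasted (433), young refed (441), old fasted (728) or old refed Paneth (720). Of the 17 named calls, 13 held without any 1 library. Calls were lost without young fasted (4, 0.19), young refed (4, 0.188), old fasted (2, 0.126) and old refed Paneth (2, 0.125) (number lost, highest edgeR adjusted p). Without the doubtful libraries 2275 genes passed (2119 shared), and 1 named call was lost (edgeR adjusted p up to 0.0644). With the run of title numbers as a term 420 genes passed and 3 of the named calls were lost (adjusted p up to 0.183 by edgeR).

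**Figure D3:**
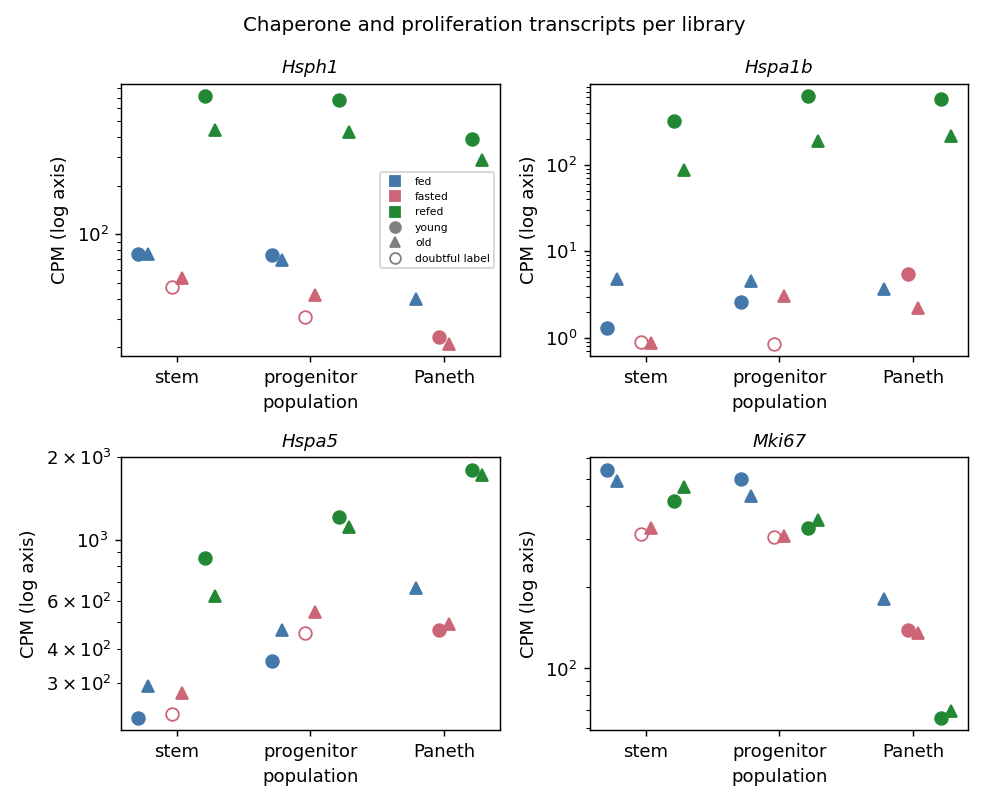
CPM (log axis, TMM-normalised) of Hsph1, Hspa1b, Hspa5 and Mki67 in each of the 17 libraries compared, by population (x axis) and diet (blue fed, red fasted, green refed), with circles for young and triangles for old mice. Hsph1 in stem cells was at 50.5 ± 4.94 CPM fasted and 579 ± 193 CPM refed (mean ± SD, n = 2 each).

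Refed libraries were then compared with fed ones. In fed libraries the mitochondrially encoded share was 6.87% (young) and 5.78% (old) in stem cells, 7.03% and 5.28% in progenitors and 2.19% in old Paneth cells, above each refed library of that age. In stem cells Me1 stood at 13.7 ± 3.45 against 2.98 ± 0.829 CPM (mean ± SD, n = 2 each, log2 difference 2.20, SE 0.13) and Acadl at 1.91, whereas Pdk4 lay below the fed level (-1.64). Hspa1a and Hsph1 were at 5.89 and 2.92, Srm at 1.27, Insig1 at 1.25, Nos2 at -1.49 and Gsdmc4, whose reads near-identical copies may share, at -3.79. Adjusted p was 1.2e-05 to 0.036 (edgeR). Both ages shared the sign, and Mki67 was at -0.23 (0.217). On the unfolded protein response list 16 of 19 rose (17 up adjusted over the list alone, median 0.74, camera adjusted p = 4.45e-20) and on the mitosis list 18 of 25 fell (23 down adjusted over the list alone, median -0.53, camera adjusted p = 1.94e-19). These had adjusted p = 0.371 with an estimated correlation. Among PPAR targets, 7 of 22 rose and 1 fell (9 up and 1 down adjusted over the list alone, median 0.86, camera adjusted p = 2.59e-10, or 0.403 with an estimated correlation). In all, 796 genes were higher and 497 lower, against 586 and 601 with upper-quartile factors and 634 in all by DESeq2. The count of 1293 moved over 1.5 times without young fed (83), young refed (64), old fed (497) or old refed stem (566). Of the 14 named calls, 5 held without any 1 library. Losses of calls came without young fasted stem 1 (1, 0.0646), young fed (7, 0.304), young refed (8, 0.263), old fed (2, 0.13), old fasted (1, 0.0645) and old refed stem (2, 0.104), and with no expression filter (1, 0.0685) and no age term (8, 0.371) (number lost, highest edgeR adjusted p). Leaving out the doubtful libraries, 825 genes passed (792 shared), and 0 named calls were lost.

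In progenitors Cyp4a10 (5.84), Me1 (3.36, 87.8 ± 26.8 against 8.48 ± 2.07 CPM, mean ± SD, n = 2 each, SE 0.11), Hspa1a (6.63), Hsph1 (2.93) and Insig1 (1.46) stood above and Gsdmc4 (-2.87), Olfm4 (-1.58) and Mki67 (-0.45) below the fed level. Adjusted p was 1.85e-08 to 0.028 (edgeR). Both ages shared the sign, and Pdk4 did not pass (0.39, 0.307). Among PPAR targets, 13 of 22 rose (19 up adjusted over the list alone, median 1.22, camera adjusted p = 3.39e-28) and on the unfolded protein response list 16 of 19 rose (19 up adjusted over the list alone, median 0.91, camera adjusted p = 7.54e-24). They had adjusted p = 0.249 with an estimated correlation. On the mitosis list 24 of 25 fell (25 down adjusted over the list alone, median -0.74, camera adjusted p = 4.95e-29), and on the stem list 9 of 25 fell (17 down adjusted over the list alone, median -0.61, camera adjusted p = 1.06e-11). Camera gave adjusted p = 0.249 and 0.401 with an estimated correlation. Young fed progenitor was stem-rich, and in the old pair the stem-list level went from 5.69 to 5.49. The 8 Paneth transcripts took 0.757% (young) and 0.983% (old) of refed against 0.269% and 0.217% of fed counts. On the tuft list 8 of 16 rose (10 up adjusted over the list alone, median 0.97, camera adjusted p = 4.19e-08, or 0.275 with an estimated correlation). In all, 1073 genes were higher and 760 lower, against 781 and 1007 with upper-quartile factors and 1179 in all by DESeq2. The count of 1833 moved over 1.5 times without young fed (215) or young refed progenitor (207). Of the 14 named calls, 6 held without any 1 library. Genes failed without young fed (7, 0.397), young refed (7, 0.294), old fed (1, 0.0588) and old refed progenitor (2, 0.0962), and with no expression filter (2, 0.0913), no age term (4, 0.16) and a separate fit per population (4, 0.158) (number lost, highest edgeR adjusted p). On the undisputed libraries alone, 1349 genes passed (1250 shared), and 0 named calls were lost.

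In Paneth cells, with 1 fed library, Hsph1 stood above the fed level (2.92, SE 0.43, 1 matched pair), as did Hspa1a (6.55) and Dnajb9 (1.76). The centromere protein Cenpa (-2.40), Birc5 (-2.26), Kif11 (-2.15), Mki67 (-1.40), Oxct1 (-1.69) and Uqcrc2 of the respiratory chain (-0.76) stood below it. Adjusted p was 9.87e-05 to 0.012 (edgeR), and Pdk4 was at -0.96 (0.0881). On the mitosis list 24 of 25 fell (24 down adjusted over the list alone, median -1.75, camera adjusted p = 2.82e-63, or 0.164 with an estimated correlation). Beside it, on the stem list 6 of 25 fell (8 down adjusted over the list alone, median -0.47, camera adjusted p = 0.000713, or 0.957 with an estimated correlation), with Olfm4 at -1.93 (edgeR adjusted p = 0.0163, 1445 to 352 CPM in the old pair). On the oxidative phosphorylation list 34 of 76 fell (58 down adjusted over the list alone, median -0.57, camera adjusted p = 4.54e-20, or 0.601 with an estimated correlation). In all, 380 genes were higher and 937 lower. The count of 1317 moved over 1.5 times without young fasted (810), young refed (808), old fasted (806) or old refed Paneth (146). Of the 12 named calls, 6 held without any 1 library but old fed Paneth. Calls were lost without old refed Paneth (6, 0.602), and with no expression filter (1, 0.119) and no age term (3, 0.101) (number lost, highest edgeR adjusted p). DESeq2 lost Aen (adjusted p = 0.127). Without the doubtful libraries 1147 genes passed (1024 shared), and 2 named calls were lost (edgeR adjusted p up to 0.0587). With the run of title numbers as a term 800 genes passed.

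Old against young mice differed in few genes, with diet as a term. The mitochondrially encoded share was lower in the old library at each diet compared in stem and Paneth cells. In stem cells the surface protein Cd177 was at 44.6 ± 19.4 CPM in old and 16.98 ± 9.31 CPM in young libraries (mean ± SD, n = 3 each, log2 difference 1.44, SE 0.12). Nos2 differed by 1.64, the interferon-induced Ly6e by 1.49, Nox1 by 1.22, the immunoproteasome subunit Psmb8 by 0.61 and Nfkbia by 0.57. Lower were Rps4y2 (-3.28), a copy of a ribosomal protein gene whose reads may be shared, Nrn1 (-1.09) and Me1 (-0.58). Adjusted p was 3.3e-06 to 0.0414 (edgeR). The sign was the same in 3 of 3 diets. Lgr5 and Olfm4 were at -0.08 and 0.01 (0.989 and 0.999), and turned to 0.17 without young fed or old fed stem (Lgr5) and to -0.16 without young fasted stem 1 or old fasted stem (Olfm4). On the MHC class II list 0 of 7 passed (6 higher adjusted over the list alone, median 0.52, camera adjusted p = 2.17e-14), on the antimicrobial and inflammation list 2 of 15 were higher (8 higher adjusted over the list alone, median 0.67, camera adjusted p = 9.19e-16), and on the MHC class I list 1 of 11 was higher (4 higher adjusted over the list alone, median 0.25, camera adjusted p = 5.35e-08). With an estimated correlation, adjusted p = 0.307. On the stem list 1 of 25 was lower (1 lower adjusted over the list alone, median -0.08, camera adjusted p = 0.00472, or 0.833 with an estimated correlation). The stem list lost its call without young fed or old fed stem (adjusted p = 0.584 and 0.578, median 0.03 in both). In all, 21 genes were higher and 9 lower. The count of 30 moved over 1.5 times without young fasted stem 1 (3), young fed (3), young refed (15), old fed (3), old fasted (3) or old refed stem (15). Of the 9 named calls, 2 held without any 1 library. Losses of calls came without young fasted stem 1 (7, 0.532), young fed (6, 0.234), young refed (3, 0.185), old fed (6, 0.244), old fasted (7, 0.534) and old refed stem (3, 0.185), and with no diet term (8, 1) and a separate fit per population (1, 0.148) (number lost, highest edgeR adjusted p). DESeq2 lost Me1 (adjusted p = 0.167). Leaving out the doubtful libraries, 6 genes passed (4 shared), and 6 named calls were lost (edgeR adjusted p up to 0.698).

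In progenitors Cd177 was at 1.31 (SE 0.12, 34.6 ± 16.4 against 13.5 ± 4.82 CPM, mean ± SD, n = 3 each), Ly6e at 1.15, Psmb8 at 0.54, Nfkbia at 0.51 and the class II genes H2-DMb1, Cd74 and H2-Eb1 at 0.80, 0.76 and 0.69. Lower in old mice were Rps4y2 (-3.47), Nrn1 (-1.10) and Me1 (-0.61), and the tuft genes Alox5 (-1.70), Sh2d6 (-1.67) and Trpm5 (-1.12). Adjusted p was 1.52e-06 to 0.0296 (edgeR). The sign was the same in 3 of 3 diets. On the MHC class II list 3 of 7 were higher (6 higher adjusted over the list alone, median 0.71, camera adjusted p = 4.8e-19) and on the antimicrobial and inflammation list 1 of 15 was higher (3 higher adjusted over the list alone, median 0.76, camera adjusted p = 1.93e-09). These had adjusted p = 0.195 and 0.35 with an estimated correlation. On the tuft list 4 of 16 were lower (13 lower adjusted over the list alone, median -1.25, camera adjusted p = 5.85e-29), and on the Paneth list 1 of 22 was lower (4 lower adjusted over the list alone, median -0.99, camera adjusted p = 9.01e-12), with the 8 Paneth transcripts at 2.70% of the counts of young fasted and 0.368% of old fasted progenitor. They had adjusted p = 0.195 and 0.468 with an estimated correlation. In all, 19 genes were higher and 25 lower. The count of 44 moved over 1.5 times without young fed (24), young fasted (6), young refed (146), old fed (26), old fasted (5) or old refed progenitor (145). Of the 13 named calls, 2 held without any 1 library. Genes failed without young fed (8, 0.182), young fasted (11, 0.307), old fed (7, 0.177) and old fasted progenitor (11, 0.365), and with no diet term (12, 1) and a separate fit per population (9, 0.174) (number lost, highest edgeR adjusted p). On the undisputed libraries alone, 4 genes passed (2 shared), and 11 named calls were lost (edgeR adjusted p up to 0.437).

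In Paneth cells Cd177 (1.04, SE 0.17, 30.5 ± 10.5 CPM, n = 3, against 12.3 ± 4.28 CPM, n = 2, mean ± SD) and the protease Ctsh (0.60) were higher in old mice. Rps4y2 (-3.47), Slc28a2 (-2.93), the brush border protease Mep1a (-2.10), Nos2 (-1.62), Nrn1 (-1.53), Me1 (-1.15) and the tuft genes Alox5 (-1.19) and Avil (-1.01) were lower. Adjusted p was 0.00176 to 0.0296 (edgeR), with the same sign in both diets held by both ages, and Lyz1 and Mmp7 were at 0.45 and 0.04 (0.867 and 0.991, Mmp7 at -0.07 without young refed or old refed Paneth). Within the refed pair, both of the later run of title numbers and without replicates, the log2 differences were 0.96 for Cd177, -1.63 for Nos2, -1.01 for Me1 and -3.23 for Slc28a2. With the run as a term 13 genes passed, and 9 of the 10 named calls were lost (adjusted p up to 0.502 by edgeR). On the enterocyte list 1 of 24 was lower (6 lower adjusted over the list alone, median -1.04, camera adjusted p = 6.13e-16, or 0.571 with an estimated correlation). On the tuft list 5 of 16 were lower (16 lower adjusted over the list alone, median -1.01, camera adjusted p = 2.83e-36, or 0.102 with an estimated correlation) and on the Paneth list 1 of 22 was lower (2 lower adjusted over the list alone, median -0.01, camera adjusted p = 0.292). That last list passed camera without young refed or old refed Paneth (adjusted p = 0.045 and 0.0433). In all, 6 genes were higher and 47 lower. The count of 53 moved over 1.5 times without young fasted (15), young refed (6), old fasted (15) or old refed Paneth (6). Of the 10 named calls, 0 held without any 1 library. Calls were lost without young fasted (9, 0.51), young refed (8, 0.357), old fasted (9, 0.507) and old refed Paneth (8, 0.354), and with no diet term (10, 1) (number lost, highest edgeR adjusted p). Without the doubtful libraries 33 genes passed (27 shared), and 3 named calls were lost (edgeR adjusted p up to 0.0798).

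**Figure D4:**
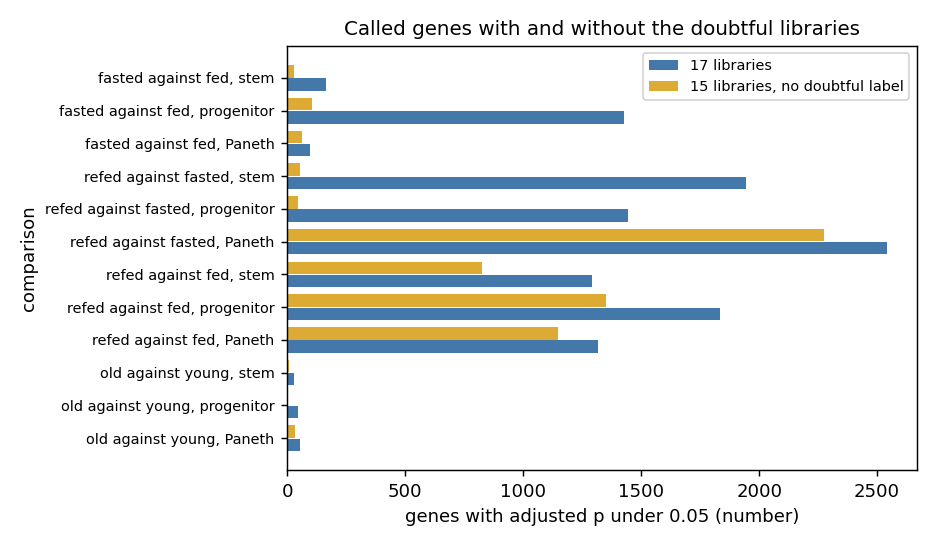
Number of genes with an adjusted p under 0.05 (x axis) in each comparison within a population, with all 17 libraries that entered (blue bars) and with the 15 libraries of undisputed label (yellow bars). Fasting in progenitors goes from 1425 to 105 genes and refeeding against fasting in Paneth cells from 2540 to 2275.

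Tested directly, the age difference of progenitors and of stem cells differed in 0 genes by edgeR's quasi-likelihood test (287 at an unadjusted p under 0.05, smallest adjusted p 0.628, 0 by DESeq2). Between Paneth and stem cells it differed in 4 genes (1042 at an unadjusted p under 0.05, 26 by DESeq2). They lie outside the rule for named genes and were chosen after seeing their values. Nos2 was at -3.26 (SE 0.31), Plcg2 at -1.20, 4930539E08Rik at -1.69 and ENSMUSG00000100801 at -1.26 (edgeR adjusted p 0.00342 to 0.0114). Age and run coincide in stem but not in Paneth libraries, so the run may add to these differences. The count of 4 moved over 1.5 times without young refed stem (2), young refed Paneth (0), old refed stem (2) or old refed Paneth (0). Of the 4 named calls, 0 held without any 1 library. Losses of calls came without young fed stem (1, 0.0798), young fasted stem 1 (1, 0.0647), young fasted Paneth (2, 0.156), young refed stem (2, 0.0839), young refed Paneth (4, 0.241), old fed stem (1, 0.0808), old fasted stem (1, 0.0684), old fasted Paneth (2, 0.144), old refed stem (2, 0.0855) and old refed Paneth (4, 0.239), and with no diet term (4, 1) (number lost, highest edgeR adjusted p). Leaving out the doubtful libraries, 1 gene passed (1 shared), and 3 named calls were lost (edgeR adjusted p up to 0.157).

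Whether age changes the fasting response rests on 1 library per age, diet and population and has no test. In stem cells the median log2 rise of the PPAR target list with fasting was 2.14 in young and 1.33 in old mice. The median difference of its members, -0.53, lay at percentile 0 of the random lists. Also at percentile 0 were the goblet (-1.998), enteroendocrine (-1.75), enterocyte (-1.13), gluconeogenesis and sugar transport (-0.57), ribosomal protein (-0.45), oxidative phosphorylation (-0.37) and fatty acid oxidation lists (-0.37), and at percentile 100 the stem (0.28) and MHC class II lists (0.46). In progenitors the PPAR medians were 2.87 in young and 2.02 in old mice, with a member difference of -0.58. At percentile 0 with it were the Paneth (-2.64), enterocyte (-1.29), goblet (-1.11), tuft (-0.88), gluconeogenesis and sugar transport (-0.51), fatty acid oxidation (-0.41), ribosomal protein (-0.34) and oxidative phosphorylation lists (-0.30), and at 100 the stem (0.50) and mitochondrially encoded lists (0.35). Genes, not libraries, were drawn, so the cell mix of 1 library can give such values. The young fasted libraries used are both doubtful, and young Paneth cells have no fed library.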

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

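The tests that weigh explanations here, and the splits that part matched libraries, were chosen only after the results were seen, whereas the other splits of the libraries were set before.

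The library labelled young fasted stem 2 had a mean of 13.40 over the 8 Paneth transcripts. A mislabelled sample could account for this, and 25 of 25 stem-list genes were nearer to the Paneth than to the stem level. Paneth cells carried over into a stem sort would leave stem RNA in the library, and the median share of stem RNA over 23 genes was 0.48% (quartiles -1.35 and 2.41), so this is excluded. A fasting effect in stem cells is excluded by the other fasted stem libraries, with young fasted stem 1 at 5.87. No group is inferred for the library.

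The young fasted progenitor library held more Paneth and tuft transcripts than other progenitors. Cells of the Paneth gate mixed in could account for this, with a median share of 8.37% over 39 genes (quartiles 6.997 and 9.55). A mislabelled Paneth library is excluded, since the 8 Paneth transcripts took 2.70% of its counts against 24.3% in the lowest Paneth library. Fasting at a young age may also act, and with 1 library of that kind it cannot be told apart.

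Chaperone transcripts were higher after refeeding in all 3 populations. Reads shared between Hspa1a and Hspa1b could not produce this, since the sum of the pair rose by at least 5.90 in every matched pair. A response to cell dissociation may add to it. Of 18 immediate early genes outside heat shock genes, 1 was called higher and 4 lower in stem cells. In progenitors this was 0 and 1, in Paneth cells 3 and 1. Diet differs here too, so the counts cannot decide this. Collection at another time of day could change clock genes, of which 9 calls were made over the 3 populations, and this cannot be told apart. Refeeding itself was not weighed by a test, and the collection day is not given.

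In Paneth relative to stem cells, the fasting response was -2.49 for Fkbp11, 1.64 for ENSMUSG00000097142, 1.45 for ENSMUSG00000098557 and -2.63 for ENSMUSG00000100801. The age difference, to which the run may add, was -3.26 for Nos2, -1.20 for Plcg2, -1.69 for 4930539E08Rik and -1.26 for ENSMUSG00000100801.

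Between populations, the splits that part every pair of libraries of the same age and diet, as the real split does, number 16 for Paneth and stem and 16 for progenitor and stem libraries. These are too few for a share under 0.05, and the real values were 10366 (highest other 9591) and 6621 (highest other 1). The split with 9591 genes is the real one with its sign turned in all 4 pairs. Of 100 splits drawn without regard to pairs, the highest others were 9591 and 4746. For age, with 10 splits each, the splits are too few for a share under 0.05, and the real values were 30 in stem cells (highest other 1) and 44 in progenitors (highest other 31).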

How the results depend on the processing

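The alternative settings were chosen before the results were seen, except where a sentence says otherwise. Libraries were matched by age and diet between populations. No paired analysis was possible by animal because the labels do not link libraries to animals. The cause of a change was not tested. Of the named genes, a fit per population or DESeq2 gave no value for Hspa1a, Cyp4a10, Gsdmc4, Phlda3, Alox5 or Rps4y2 in some comparisons, and leaving out old fed Paneth is not estimable for fasted or refed against fed Paneth cells or the fasting response of Paneth relative to stem cells.

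With all 18 libraries as labelled the counts of called genes were for progenitors against stem cells 3248, fasted against fed 1 in stem cells, 2 in progenitors, 0 in Paneth cells, refed against fasted 48 in stem cells, 8 in progenitors, 5 in Paneth cells, refed against fed 1 in stem cells, 1 in progenitors, 0 in Paneth cells, old against young 1 in stem cells, 1 in progenitors, 1 in Paneth cells, the fasting response 0 in Paneth relative to stem cells and the age difference 0 in Paneth relative to stem cells. There the direction turned for the goblet cell list to -1.77 and the enteroendocrine cell list to -1.94 (refed against fasted in stem cells), Lgr5 to 0.26 and the stem list to 0.16 (old against young in stem cells) and ENSMUSG00000097142 to -1.61 and ENSMUSG00000098557 to -1.81 (fasting response in Paneth relative to stem cells). Of the named gene calls, 5 of 13 were lost there for progenitors against stem cells, and 0 to 5 were kept in each other comparison that lost calls. Camera's adjusted p rose past the threshold there for the tuft cell list 0.244, the Paneth list 0.103 and the DNA replication list 0.142 (progenitors against stem cells), the tuft cell list 0.205 (refed against fasted in progenitors) and the stem list 0.102 (refed against fed in Paneth cells), and fell below it for the stem list 2.1e-05 (fasted against fed in stem cells) and the mitosis list 0.00515 (refed against fasted in stem cells). With no covariate the count was for progenitors against stem cells 4372. With no expression filter the counts were for fasted against fed 432 in stem cells, 432 in Paneth cells, old against young 170 in stem cells, 286 in progenitors, 313 in Paneth cells, the fasting response 182 in progenitors and 173 in Paneth relative to stem cells and the age difference 5 in progenitors and 110 in Paneth relative to stem cells. Without the 3 doubtful libraries the counts were for fasted against fed 27 in stem cells, 105 in progenitors, 64 in Paneth cells, refed against fasted 55 in stem cells, 44 in progenitors, refed against fed 825 in stem cells, old against young 6 in stem cells, 4 in progenitors, 33 in Paneth cells, the fasting response 1 in Paneth relative to stem cells and the age difference 1 in Paneth relative to stem cells. The direction turned there for Lgr5 to 0.20 and the stem list to 0.03 (fasted against fed in stem cells) and Olfm4 to -0.17 (old against young in stem cells). With no age term the counts were for fasted against fed 108 in stem cells, 845 in progenitors, 59 in Paneth cells and the fasting response 1 in progenitors and 0 in Paneth relative to stem cells. There the direction turned for the MHC class I presentation list to 0.05 (refed against fed in Paneth cells). With a separate fit per population the counts were for fasted against fed 259 in stem cells, 475 in progenitors, 379 in Paneth cells, refed against fasted 464 in progenitors, refed against fed 851 in progenitors and old against young 61 in stem cells, 13 in progenitors, 373 in Paneth cells. With the run of title numbers as a term, added after seeing the data, Paneth counts were 35 for fasted against fed. They were 420 for refed against fasted, 800 for refed against fed and 13 for old against young. With upper-quartile factors the count was for the fasting response 2 in progenitors relative to stem cells. With DESeq2 the counts were for refed against fasted 874 in stem cells, 678 in progenitors, 1625 in Paneth cells, refed against fed 634 in stem cells, 1179 in progenitors, old against young 53 in stem cells, 76 in progenitors, 125 in Paneth cells, the fasting response 34 in progenitors and 16 in Paneth relative to stem cells and the age difference 26 in Paneth relative to stem cells. With no diet term the counts were for old against young 2 in stem cells, 1 in progenitors, 0 in Paneth cells and the age difference 0 in Paneth relative to stem cells. The direction turned there for Olfm4 to -0.03 (old against young in stem cells) and Mmp7 to -0.10 (old against young in Paneth cells). With RLE factors, DESeq2 or no expression filter the direction turned for Olfm4 to 0.00 (old against young in stem cells). Camera's direction turned, but not the median, for 2 lists. The fatty acid synthesis list (fasted against fed in stem cells) kept a negative median (-0.09 with the 17 libraries), at -0.18 with all 18 libraries as labelled. The Paneth list (fasted against fed in Paneth cells) kept a negative median (-0.08 with the 17 libraries), at -0.10 with no expression filter, -0.08 without the 3 doubtful libraries, -0.08 with no age term, -0.07 with a separate fit per population (adjusted p = 0.0276) and -0.06 with upper-quartile factors.

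Leaving out 1 library at a time, the lowest and highest counts were for fasted against fed 31 to 144 in stem cells, 182 to 1877 in progenitors, 14 to 36 in Paneth cells, refed against fasted 112 to 1645 in stem cells, 101 to 1797 in progenitors, 433 to 2538 in Paneth cells, refed against fed 64 to 1100 in stem cells, 207 to 1954 in progenitors, 146 to 810 in Paneth cells, old against young 3 to 15 in stem cells, 5 to 146 in progenitors, 6 to 53 in Paneth cells, the fasting response 0 to 178 in progenitors and 1 to 4 in Paneth relative to stem cells and the age difference 0 to 6 in Paneth relative to stem cells. Directions turned for log2 values that ranged as follows. Fasted against fed, Lgr5 was -0.40 to 0.36 and the stem list -0.24 to 0.13 in stem cells. In that comparison Lgr5 was -1.54 to 0.10 in progenitors and Lyz1 -0.30 to 0.14 in Paneth cells. The mitosis list was -0.12 to 0.23 (refed against fasted, stem cells). The p53 target list was 0.07 to 0.20 (refed against fed, Paneth cells, camera's direction only, not the median). Old against young, Lgr5 was -0.24 to 0.17 and Olfm4 -0.16 to 0.16 in stem cells, and Mmp7 -0.07 to 0.14 in Paneth cells. The median, but not camera's direction, turned for the Paneth list (fasted against fed in Paneth cells) to 0.11 without old fasted Paneth, the stem list (old against young in stem cells) to 0.03 without young fed or old fed stem and the Paneth list (old against young in Paneth cells) to 0.01 with upper-quartile factors and 0.12 without young fasted or old fasted Paneth or with the run of title numbers as a term.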

Other observations

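The tests used here were set before the results were seen, except where a choice is named as later.

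Some genes of the p53 response and of antigen presentation stood above the fed level in refed stem cells and progenitors. In stem cells the nuclease Aen was at 1.24, Phlda3 at 2.03 and Ccng1 at 0.64, in progenitors at 0.72, 1.53 and 0.54, and in Paneth cells Aen and Ccng1 were at 0.61 and 0.59. The class I activator Nlrc5 was at 1.40 in stem cells and 1.37 in progenitors, Psmb8 at 0.59 in stem cells, and Igtp and H2-K1 at 1.75 and 0.57 in progenitors. Adjusted p was 0.000128 to 0.00668 in stem cells, 0.000844 to 0.0305 in progenitors and 0.0295 to 0.0347 in Paneth cells (edgeR's quasi-likelihood test). On the p53 target list in stem cells 5 of 17 rose (7 up and 1 down adjusted over the list alone, median 0.30, camera adjusted p = 0.00196) and in progenitors 4 of 17 rose (4 up adjusted over the list alone, median 0.24, camera adjusted p = 0.00801). Camera gave adjusted p = 0.403 and 0.457 with an estimated correlation. On the MHC class I list in stem cells 4 of 11 rose (5 up adjusted over the list alone, median 0.16, camera adjusted p = 0.00486) and in progenitors 6 of 11 rose (7 up adjusted over the list alone, median 0.52, camera adjusted p = 1.82e-05). With an estimated correlation, adjusted p = 0.504 and 0.299. On the interferon list in stem cells 3 of 35 rose (5 up adjusted over the list alone, median 0.21, camera adjusted p = 0.034) and in progenitors 11 of 35 rose (14 up adjusted over the list alone, median 0.73, camera adjusted p = 1.82e-08). These had adjusted p = 0.567 and 0.249 with an estimated correlation. In Paneth cells, on the p53 target list 2 of 17 rose and 1 fell (3 up and 3 down adjusted over the list alone, median 0.16, mean -0.04, camera's direction up, camera adjusted p = 0.343) and on the MHC class I list 2 of 11 fell (1 up and 3 down adjusted over the list alone, median -0.21, camera adjusted p = 0.41). That last list passed camera as lower with no expression filter (median -0.24, adjusted p = 0.0419), and its median turned to 0.05 with no age term. The interferon call in stem cells was lost without young refed or old fed stem (camera adjusted p = 0.131 and 0.201) and with no age term (0.115), which also ended the MHC class I call there (0.133), and the p53 call in progenitors without young fed progenitor (0.116). Gene calls were lost without young fed stem (Phlda3, Ccng1, Nlrc5 and Psmb8, edgeR adjusted p up to 0.139), young refed stem (these 4, up to 0.134), old fed or old refed stem (Phlda3, 0.0559 and 0.0782), young fed progenitor (Phlda3, Nlrc5 and H2-K1, up to 0.397), young refed progenitor (these and Ccng1, up to 0.281), old fed progenitor (Ccng1, 0.0588), old refed progenitor (Phlda3, 0.0796) and old refed Paneth (Aen 0.581, Ccng1 0.453). With no age term the calls of Phlda3, Nlrc5 and Psmb8 were lost in stem cells, of Phlda3, Nlrc5 and H2-K1 in progenitors and of Aen and Ccng1 in Paneth cells. H2-K1 was also lost with a separate fit per population, and Aen in Paneth cells by DESeq2 and without the doubtful libraries.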
